A study of Homo sapiens with 8 samples.

How the data were processed

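Gene expression of 8 samples of the MCF10A cell line, 4 with an empty retroviral vector and 4 with human HER2 cDNA, was measured on 1-colour Illumina bead arrays, 1 array per sample. Per the labels, biotin-labelled cRNA was made from total RNA, and both groups grew in the same medium. The deposited non-normalized table gives, per the file headers, an intensity and a detection p-value for each of 47323 probes on each array. Its lowest intensities lie well above 0, so the background is still in them. The detection p-value of the deposited table was taken as that against the array's negative control beads. A second deposited table holds the authors' processed intensities of the same arrays. Its 8 columns share 1 distribution (median 92.8, highest value 21125) and each has the ranks of its non-normalized column (Spearman 1), which is what quantile normalization on the linear scale without background subtraction gives; this was read from the values, and no header states it. The submitters' processing notes name the package lumi, with no role or order. The scanner software is not given in the sources used here. Columns were matched to samples by name; 1 intensity column, HER_2, was read as HER2 replicate 2 with a digit missing, since the other HER2 columns carry the numbers 1, 3 and 4. There were 0 unused sample columns.

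The non-normalized intensities were processed in limma 3.58.1 (R 4.3.3) with neqc, which estimates the background from the detection p-values, adds an offset of 16, normalizes between arrays by quantiles and takes log2. A probe was kept if its detection p was under 0.01 on at least 4 arrays, which left 14227 probes. The platform annotation gave 1 gene symbol to 30113 probes and several to 8, and 17202 probes are not listed in it and are unnamed here. Entrez identifiers of 30074 probes matched the RefSeq gene table, and 0 symbols changed. Of the probes kept, 11573 had 1 symbol and 2654 had no usable name. Each gene was represented by its brightest probe over all arrays, giving 8956 genes; among 2192 genes with several detected probes, 0 had probes that passed in opposite directions, and in 105 some but not all probes passed. The number of arrays, 4 per group, limits the precision.

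Groups were compared with lmFit and eBayes on all 8 samples without covariates, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. ERBB2 and array-level values were also tested by exact two-sided permutation over the 70 assignments of samples to groups. Where a gene was detected on 0 arrays of a group, only a bound is given. It is the mean of the brighter group against the mean, in the dim group, of the higher of each array's lowest detected value and the probe's own value, written as at least N-fold in the text, while the plots and the ranking of genes use the fitted values. The adjusted p of such a gene is that of the fit. Differences between experiment numbers, and between replicate labels, were tested by an interaction term. A set of 29 gene lists was tested, where at least 5 members were measured (26 lists), by camera with an inter-gene correlation of 0.01. An estimated correlation and fry were alternatives. fry asks whether a list moves one way, not whether it moves more than other genes. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named ERBB2, the 15 largest rises and the 15 largest falls among genes that passed and moved alike in all 4 pairs of equal sample number, and up to 4 members with the smallest p of each list described. Genes named outside that rule are list members given to complete a count, and genes of the closing observations chosen after their values were seen.

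The fit was tested on simulated data made from the means and spreads of the 8956 genes with 200 changed genes in 10 runs: 29.3% of changes of 0.5 on the log2 scale, 86.4% of changes of 1 and 99.2% of changes of 2 were recovered, and 4.72% of calls were false on average. The simulated noise was independent between genes and between arrays, so correlation between genes of the real arrays was not covered. For the position of the boundary on chromosome 17, 200 of 535 genes raised by 0.4 in 20 simulated runs gave a median error of 0 genes and a largest error of 2. The raised genes reached the end of the order, so the simulation did not test for a further boundary. Gene order came from the RefSeq table of assembly GRCh38.p14, which placed 8953 of the genes. No coordinates are given, since the files name no build.

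Alternatives covered the background correction (none, or normexp with an offset of 50), median scaling, the authors' values, other filters on dim probes, the treatment of several probes per gene, trend and robust variance, a test against a fold change of 1.2, array weights, blocks by sample number, experiment number or replicate label, means of the samples that share a number, a random block, and leaving out each sample. The test without the distal chromosome 17 genes was added after seeing the data.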

Results

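MCF10A is a non-tumorigenic human breast epithelial cell line. The samples were MCF10A cells transduced with an empty retroviral vector (Vector, 4 samples) or with a retrovirus holding human HER2 cDNA (HER2, 4 samples). HER2 is the receptor tyrosine kinase encoded by ERBB2, and the title of the series places the work in the study of HER2 and breast cancer stem cells. RNA of each sample was hybridised to an Illumina bead array, and 47323 probes were read. The median raw intensity lay between 86.5 and 101.3 on the 8 arrays, and 13237 to 14749 probes were detected above the negative controls. Neither measure separated the groups. The median intensity was 93.3 ± 6.89 in HER2 and 92.5 ± 4.25 in Vector (SD, n = 4 each; exact two-sided permutation p = 0.857). In HER2 14316 ± 448 and in Vector 14071 ± 568 probes were detected (exact p = 0.543). Across the 8956 genes tested, log2 intensities of arrays of the same group correlated at r = 0.972 to 0.990, and those of arrays of different groups at 0.948 to 0.969. Genes are not independent replicates, so these values describe the arrays only. The labels give each sample a replicate and an experiment number but do not say that the samples were separate cultures. All p-values therefore measure only the spread between these samples, which may be technical.

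The level of the introduced gene was read first. ERBB2 was not higher in the samples labelled HER2. The only ERBB2 probe detected, ILMN_2352131, read 8.33 ± 0.16 in the samples labelled HER2 and 8.56 ± 0.30 in Vector (log2 intensity, SD, n = 4 each), a difference of -0.23 with a 95% confidence interval of -0.58 to 0.11 (limma adjusted p = 0.478; exact two-sided permutation p = 0.257). The other probes, ILMN_1728761 and ILMN_1717902, were above background on 0 arrays of either group, so no fold was taken from them. The probes' sequences were not among the sources used here. A probe outside the introduced cDNA cannot read it, and whether the detected probe lies outside is not known. These values therefore cannot be used to check the labels or the transduction. Every direction below is that of the samples labelled HER2 against those labelled Vector.

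The question of the design was which transcripts differ between MCF10A cells with HER2 cDNA and cells with the empty vector. The largest rise in the samples labelled HER2 was that of ALOX5AP, and KLK5 and PADI4 had the largest falls. ALOX5AP, which encodes the protein that presents arachidonic acid to 5-lipoxygenase, rose 111-fold (log2 fold change 6.80 ± 0.37, SE, n = 4 each; adjusted p = 5.89e-07). The neutrophil chemokines CXCL8 and CXCL1 were at least 49.5-fold and at least 36.5-fold higher, and the acute-phase protein gene SAA1, detected on 1 of 4 Vector arrays, rose by 6.18 ± 0.25 (log2, SE; adjusted p = 4.32e-08), each at its brightest probe. The less bright probes gave at least 16.95-fold for CXCL8 and at least 13.3-fold and at least 5.71-fold for SAA1. KLK5, a serine protease of stratified epithelia, was at least 17.3-fold lower (adjusted p = 0.000152; at least 7.72-fold at its other probe), and PADI4, an enzyme that converts arginine to citrulline in proteins, fell by 4.51 ± 0.63 (log2, SE; adjusted p = 0.00118; detected on 3 of 4 HER2 arrays). In all, 602 of 8956 genes passed adjusted p = 0.05 in limma, 384 higher and 218 lower in the samples labelled HER2, and each of the 602, selected on these same samples, differed in the same direction in all 4 pairs of equal sample number. Of these, 142 were higher and 66 lower by at least 1 on the log2 scale, and 46 were higher and 12 lower by at least 2. The count was smaller whichever array was left out, from 596 genes without Vector replicate 4 down to 373 (253 higher, 120 lower) without HER2 replicate 2. Without Vector replicate 2, 141 genes were lower. Genes that passed and lay at least 1 apart on the log2 scale numbered 208 in the background-corrected data. They numbered 105 with the authors' normalized values, which keep the background and give smaller folds. With those values 592 genes passed in all, and 518 of the 602 kept their call.

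Further large rises were those of the coagulation inhibitor TFPI (4.97 ± 0.21, log2, SE), the alarmin subunits S100A8 (4.78 ± 0.55) and S100A9 (3.71 ± 0.37), the cytokine IL1A (4.57 ± 0.29), the secreted protease-inhibitor family member WFDC2 (4.37 ± 0.28) and the chemokines CCL20 (4.08 ± 0.15) and CXCL2 (3.89 ± 0.26). TNFAIP3, which encodes the A20 inhibitor of NF-kB signalling, was at least 9.24-fold higher, and PDZK1IP1 at least 7.46-fold. C1QTNF1, which lies in the distal part of chromosome 17 described further on, rose by 3.65 ± 0.23, and the atypical chemokine receptor ACKR3 by 3.60 ± 0.37. Among the falls, KLK6 and KLK7 were at least 6.38-fold and at least 3.69-fold lower, and DENND2D at least 2.75-fold. The matrix proteins MGP (-3.35 ± 0.33) and FBLN1 (-2.48 ± 0.30), the carbonic anhydrase CA2 (-2.50 ± 0.18) and the basal keratin KRT15 (-2.45 ± 0.50) fell. C5orf46 (-2.62 ± 0.27), the cell cycle regulator RGCC (-2.39 ± 0.21), SYBU (-2.12 ± 0.34), SMOC1 (-1.95 ± 0.40), NCCRP1 (-1.94 ± 0.40) and the cyclin CCNA1 (-1.84 ± 0.36) completed the 15 largest falls. Not all arrays of the lower group measured these genes: IL1A was detected on 1 Vector array, WFDC2, CXCL2 and ACKR3 on 2 and C1QTNF1 on 3. MGP and C5orf46 were detected on 1 HER2 array, and FBLN1, RGCC, SMOC1 and NCCRP1 on 3. The sizes given for these genes and for SAA1 and PADI4 therefore rest in part on readings at background. For SAA1, IL1A, CXCL2, ACKR3, MGP and C5orf46 the mean of the lower group lay under the background floor of the arrays, so their values are not exact sizes. Adjusted p in limma lay between 1.20e-08 (TNFAIP3) and 0.000244 (S100A8) for the 15 largest rises, and between 2.89e-06 (DENND2D) and 0.0129 (NCCRP1) for the 15 largest falls. Probes of a gene differed in size: TFPI rose by 4.65 ± 0.19 and at least 2.16-fold at its other probes. FBLN1 fell at all 3 of its probes (the others at -2.39 ± 0.29 and at least 1.95-fold lower), and NCCRP1 did not pass at its other probe (-0.87 ± 0.24; adjusted p = 0.0570 over all probes). The differences also depended on the background: with the authors' values, ALOX5AP differed by 5.76 in place of 6.80, IL1A differed by 2.90 in place of 4.57, MGP by -1.92 in place of -3.35 and C5orf46 by -1.32 in place of -2.62 on the log2 scale.

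**Figure D1:**
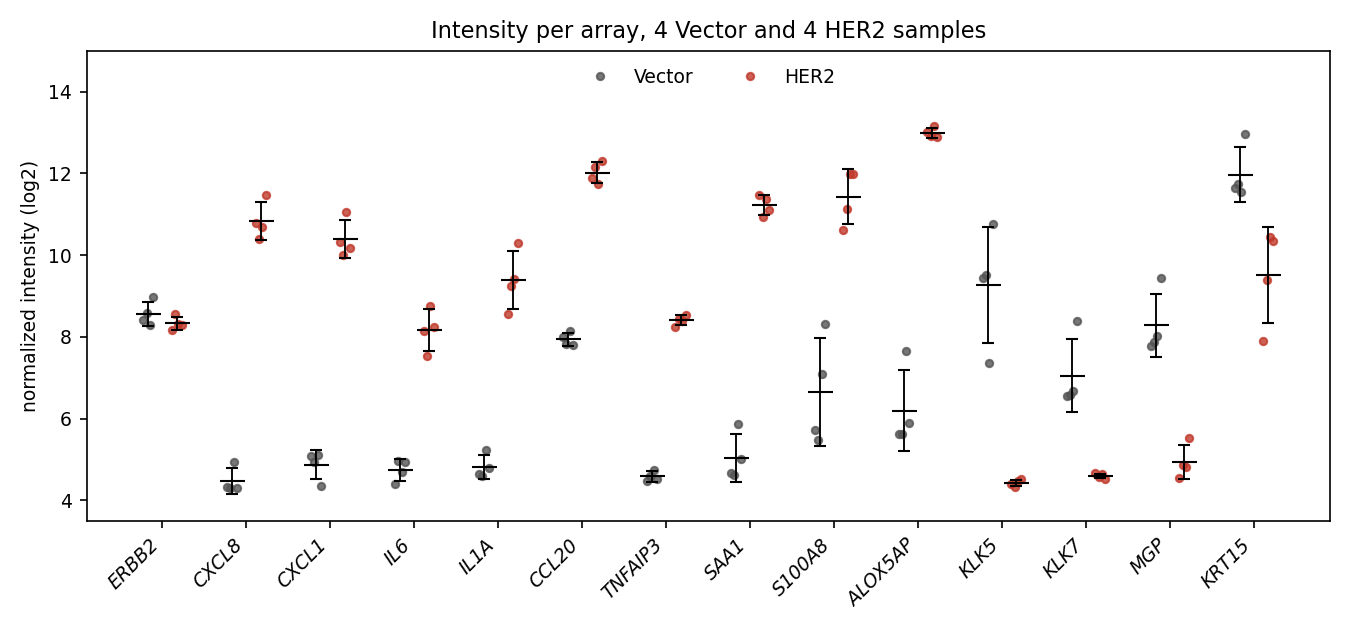
Normalized log2 intensity (y axis) of 14 genes (x axis) on the 4 Vector arrays (grey points) and the 4 HER2 arrays (red points), with the group mean and SD as bars. ERBB2 lies at 8.56 in Vector and 8.33 in HER2, while ALOX5AP lies at 6.19 and 12.99 and CCL20 at 7.94 and 12.01.

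NF-kB target cytokines and feedback genes rose as a group. Of the 17 measured members, 16 rose, 0 fell and 1 did not pass (16 rose when adjusted over the list alone), with a median log2 fold change of 2.80, or 2.20 with genes undetected in Vector set at their bound. The filter on dim probes favoured this count: 8 of the 16 risers were undetected on all Vector arrays and entered through the samples labelled HER2, and 7 further members with a probe were too dim to enter. Over all 24 members with a probe, a median looked at after the values were seen, it was 1.504, and camera without the filter gave an adjusted p of 2.42e-32. Besides CXCL8, CCL20 and TNFAIP3, CSF3 was at least 3.84-fold higher (adjusted p = 2.48e-08; at least 2.60-fold at its other probe) in the samples labelled HER2. The camera test of limma gave an adjusted p of 3.01e-34 for the list, and adjusted p = 0.00618 with an estimated correlation. Genes of the JAK-STAT3 axis also rose, in 5 of 13 measured members (9 when adjusted over the list alone; median 0.47). The other 8, which did not pass over all genes, were OSMR, CEBPD, CEBPB, BCL3, SOCS3, STAT3, PIM1 and BCL6. The acute-phase genes SAA1 and SAA2 (at least 6.34-fold) led this list, followed by the cytokine co-receptor IL6ST (0.86 ± 0.15, log2, SE) and the survival gene MCL1 (0.86 ± 0.20), which did not pass without Vector replicate 2 (adjusted p = 0.0541), Vector replicate 3 (0.0543) or HER2 replicate 2 (0.0787). Camera gave an adjusted p of 1.01e-08, and adjusted p = 0.0149 with an estimated correlation. These were the only 2 of the 26 lists tested whose call held with an estimated correlation.

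A further 5 lists passed camera with the preset correlation and not with an estimated one. Medians over all members with a probe, dim ones included, were looked at after the values were seen. The interferon list had 0.08 (0.24 over measured members) and the protease list 0.07 (0.52). The ERK, antigen presentation and cholesterol lists had 0.39, 0.32 and -0.19 (0.40, 0.34 and -0.26 over measured members). Camera without the filter passed for each of the 5. Outputs of the ERK pathway were higher (adjusted p = 4.88e-07; adjusted p = 0.286 with an estimated correlation), and 6 of 19 measured members rose (10 when adjusted over the list alone). Among them were IER3 (1.34 ± 0.13, log2, SE), MAFF (1.01 ± 0.17), the ERK phosphatase DUSP6 (1.51 ± 0.31) and MYC (0.42 ± 0.11). MYC did not pass when any 1 of the 8 arrays was left out (adjusted p = 0.0576 to 0.112). Antigen presentation genes (adjusted p = 0.00018; adjusted p = 0.349 with an estimated correlation) had 3 of 11 members that rose (6 when adjusted over the list alone): the peptide transporter TAP1 (1.56 ± 0.15), the immunoproteasome subunit PSMB8 (1.41 ± 0.22) and TAPBP (0.85 ± 0.15). Interferon-stimulated genes (adjusted p = 0.00641; adjusted p = 0.300 with an estimated correlation) had 3 of 10 that rose (4 when adjusted over the list alone), OAS3 (1.12 ± 0.13), IFIH1 (1.12 ± 0.16) and RIGI (at least 1.26-fold), the last of which did not pass with the authors' values. The list did not pass with only genes detected on all 8 arrays (6 members; adjusted p = 0.0589). The rise itself decides that filter in part, since it leaves out RIGI and ISG15, both dim in Vector. It also leaves out IFI6 (0.34) and XAF1 (-0.05), which did not pass and were each detected on 3 Vector arrays. Matrix proteases and inhibitors (adjusted p = 0.0332; adjusted p = 0.300 with an estimated correlation) had 4 of 9 that rose (5 when adjusted over the list alone): the plasminogen activators PLAU (1.49 ± 0.24) and PLAT (at least 2.41-fold), the sheddase ADAM17 (0.59 ± 0.12) and the inhibitor TIMP2 (0.77 ± 0.15), a gene of the distal part of chromosome 17. Without the genes of that part the list's adjusted p was 0.0982, and it was 0.0594 without Vector replicate 2, 0.104 without HER2 replicate 3 and 0.0513 without HER2 replicate 4. It also did not pass with means per replicate label (adjusted p = 0.101), with the mean of a gene's probes (0.109) or with other filters on dim probes (0.0529 and 0.0844). ADAM17 did not pass at its other probes (0.18 ± 0.12 and -0.01 ± 0.17), nor TIMP2 at its other one (0.42 ± 0.14). Cholesterol synthesis genes lay lower as a list (adjusted p = 0.00848; adjusted p = 0.583 with an estimated correlation; median -0.26), while 0 of 13 members passed over all genes and 2 were lower when adjusted over the list alone. MVD (-0.72 ± 0.20) and HMGCS1 (-0.49 ± 0.14) had the smallest p, and both passed without HER2 replicate 3 (adjusted p = 0.00672 and 0.0423). The list did not pass without HER2 replicate 1 (adjusted p = 0.0612).

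**Figure D2:**
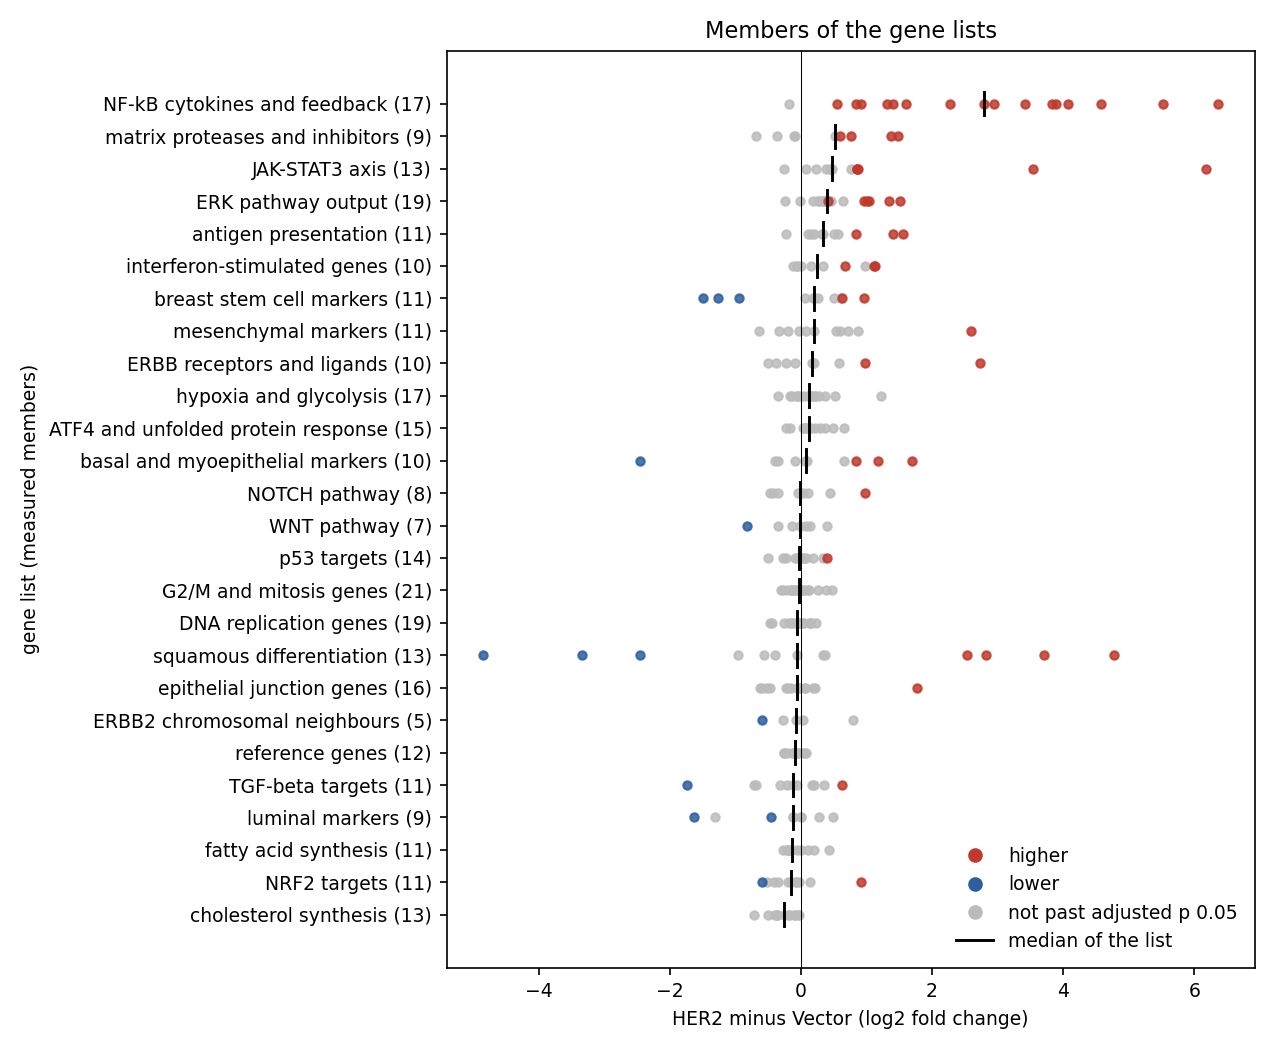
Log2 fold change, HER2 minus Vector (x axis), of every measured member of the 26 gene lists tested (y axis, with the number of members), coloured by whether it passed adjusted p = 0.05, with a black bar at each list's median. The NF-kB list has its median at 2.80, and the next highest median is 0.52, that of the matrix proteases. Over all members with a probe, dim ones included, these medians are 1.504 and 0.07.

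Breast stem cell markers moved apart. Of 11 measured members, 2 rose, the aldehyde dehydrogenase ALDH1A3 (0.62 ± 0.12, log2, SE, n = 4 each) and the surface receptor PROCR (0.96 ± 0.19). A further 3 fell, CD24 (-1.49 ± 0.30), CXCR4 (at least 1.45-fold lower) and SOX9 (-0.94 ± 0.22), the last of which lies in the distal part of chromosome 17. Adjusted over the list alone, 4 rose and 3 fell, and the list as a whole did not pass camera (adjusted p = 0.380; median 0.19, mean -0.03). The other probe of ALDH1A3 did not pass (0.39 ± 0.17). Mesenchymal markers (1 of 11 rose; 1 when adjusted over the list alone; adjusted p = 0.325) held CDH11, which was at least 4.00-fold higher. Epithelial junction genes (1 of 16 rose; 1 rose and 1 fell when adjusted over the list alone; adjusted p = 0.555) held the tight junction gene CLDN1 (1.77 ± 0.39). Among basal and myoepithelial markers, 3 of 10 rose and 1 fell (3 and 2 when adjusted over the list alone; adjusted p = 0.527). KRT14 rose by 1.70 ± 0.27, LAMB3 by 1.17 ± 0.27 and ITGB4, also of distal chromosome 17, by 0.85 ± 0.20, while KRT15 fell. Luminal markers had 0 of 9 that rose and 2 that fell, the transcription factor ELF3 (-1.63 ± 0.27) and KRT7 (-0.45 ± 0.11), or 1 and 2 when adjusted over the list alone (adjusted p = 0.390). Squamous differentiation genes moved both ways, 4 of 13 up and 3 down (4 and 6 when adjusted over the list alone; adjusted p = 0.983; median -0.05, mean 0.15). The risers were S100A8, S100A9, the siderophore-binding LCN2 (2.83 ± 0.33) and the elastase inhibitor PI3, and KLK5, KLK6 and KLK7 fell. With only genes detected on all 8 arrays, which leaves out KLK5, KLK6 and KLK7, the squamous list passed upward (10 members; adjusted p = 0.0177). With 1 array left out, CLDN1 passed only without HER2 replicate 1, HER2 replicate 3 or Vector replicate 4 (otherwise adjusted p = 0.0501 to 0.0602). ITGB4 passed only without HER2 replicate 1 or Vector replicate 4 (0.0632 to 0.101), and KRT7 only without HER2 replicate 3 or Vector replicate 3 (0.0640 to 0.0979). LAMB3 did not pass without Vector replicate 2 (0.0596), Vector replicate 3 (0.0598) or HER2 replicate 2 (0.0660).

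Receptors and ligands of the ERBB family had 2 of 10 members that rose, the ligand HBEGF (2.73 ± 0.31, log2, SE) and the feedback inhibitor ERRFI1 (0.99 ± 0.19), or 3 higher and 1 lower when adjusted over the list alone (adjusted p = 0.325). With only genes detected on all 8 arrays the list passed upward (8 members; adjusted p = 0.0176), but that filter leaves out NRG1 (-0.38) and NRG4 (-0.50), which were dim in the samples labelled HER2. Of the chromosomal neighbours of ERBB2, 0 of 5 rose and PGAP3 fell (-0.59 ± 0.15; 1 when adjusted over the list alone; adjusted p = 0.555). In the pathway lists that did not pass, DKK1 of the WNT list (7 measured; adjusted p = 0.765) fell by 0.82 ± 0.21, and JAG1 of the NOTCH list (8 measured; adjusted p = 0.842; median -0.01, mean 0.03) rose by 0.98 ± 0.18. TGFBR2 rose by 0.62 ± 0.13 and CCN2 fell by 1.74 ± 0.47 among 11 TGF-beta targets (adjusted p = 0.765). TNFRSF10B rose by 0.41 ± 0.11 among 14 p53 targets (adjusted p = 0.765, upward by camera with a median of -0.02). In the NRF2 list (11 measured; adjusted p = 0.360) ABCC3, of distal chromosome 17, rose by 0.92 ± 0.17 and NQO1 fell by 0.60 ± 0.14. Adjusted over the list alone, 1 gene rose in each of the WNT, NOTCH, TGF-beta, p53 and NRF2 lists, and 2 fell in the WNT list, 1 in the TGF-beta list and 2 in the NRF2 list. With 1 array left out, TNFRSF10B never passed (adjusted p = 0.0575 to 0.146). The other probes of DKK1 (-0.35 ± 0.26) and CCN2 (-1.02 ± 0.40) did not pass. DKK1 and CCN2 passed only without HER2 replicate 1 or Vector replicate 4 (otherwise 0.0740 to 0.113 and 0.0543 to 0.137). PGAP3 passed only without Vector replicate 1 or HER2 replicate 2 (0.0661 to 0.109), and NQO1 only without Vector replicate 1, Vector replicate 2 or HER2 replicate 1 (0.0551 to 0.0946).

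Genes of cell division did not pass: 0 of 21 G2/M and mitosis genes (adjusted p = 0.983) and 0 of 19 DNA replication genes (adjusted p = 0.765) passed, with PLK1 at 0.39 ± 0.15 and TYMS at -0.48 ± 0.21 (log2, SE). Hypoxia and glycolysis genes (17 measured; adjusted p = 0.325), ATF4 and unfolded protein response genes (15; adjusted p = 0.380), fatty acid synthesis genes (11; adjusted p = 0.801) and reference genes (12; adjusted p = 0.437) also had 0 that passed, as they had when adjusted over the list alone. PPIA (-0.25 ± 0.15) and GAPDH (-0.21 ± 0.12) had the smallest p of the reference genes. Markers of other cells were mostly below background. Of 13 leukocyte markers with a probe, 3 were measured. CD14 rose by 1.78 ± 0.26, while CD68 (-0.03 ± 0.12) and CSF1R (-0.46 ± 0.24) did not pass, and PTPRC and TYROBP were detected on 0 arrays. Of 4 fibroblast markers measured, FAP rose by 0.55 ± 0.12 and FBLN1 fell, and of 2 endothelial markers measured, PECAM1 (-1.17 ± 0.37) and ENG (0.20 ± 0.11), 0 passed. Adjusted over the list alone, CD14 and FAP were again higher, and FBLN1 and PECAM1 lower. Over all genes, FAP did not pass without Vector replicate 1 (adjusted p = 0.0507) and PECAM1 did (0.0444). Without Vector replicate 4 TYMS (0.0150), CCNE1 (0.0485) and NDRG1 (0.0322) passed, and so did the DNA replication list, downward (camera adjusted p = 0.0422).

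The comparison was also made within each experiment number. The gap between the samples labelled HER2 and Vector differed between the experiment numbers for 0 genes by limma's interaction term, with 169 genes at an unadjusted p under 0.05, and for 0 genes between the replicate labels, with 290. Both unadjusted counts are a smaller share of the 8956 genes than the 0.05 that chance alone would give. With 2 samples against 2 in each number, the 0 does not show that the gap was the same. Within experiment 1 alone (2 samples against 2) 133 genes passed, 98 higher and 35 lower, and within experiment 2 alone 220 passed, 160 higher and 60 lower. Across the 8956 genes, which are not independent replicates, the differences in the experiment numbers correlated at r = 0.810. The NF-kB list had a median of 2.67 in experiment 1 and 2.86 in experiment 2.

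The position of genes was examined after the values were seen, with gene order taken from the RefSeq annotation of GRCh38.p14. Genes of the distal long arm of chromosome 17, from PHB1 on, lay higher in the samples labelled HER2. Only 1 boundary was sought, so the part was taken to the end of the chromosome. Its last genes did not share the shift throughout: WDR45B (-0.05), RAB40B (-0.37), FN3KRP (-0.27) and TBCD (-0.01) lay below 0, RPL23AP87 at 0.06 and METRNL at 0.36. The median log2 fold change of the 198 genes tested there was 0.42, 90.4% of them lay above 0, and 69 rose while 1, SOX9, fell. Before that boundary, whose last gene was ZNF652, the 337 genes of chromosome 17 had a median of -0.06, with 6 that rose and 5 that fell. On the other chromosomes 8418 genes had a median of -0.03, and 3.67% of them rose against 34.8% in the distal part (Fisher's exact p = 1.91e-45 for the distal part against all other genes placed, with genes as units, which are not independent). By array, the median of the distal genes against the Vector mean lay between 0.36 and 0.47 in the 4 samples labelled HER2 and between -0.01 and 0.02 in the 4 Vector samples (exact two-sided permutation p = 0.0286, the smallest possible). The boundary was set from these values, so neither p allows for the search. With these genes left out of the fit, 496 genes passed, 295 higher and 201 lower.

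**Figure D3:**
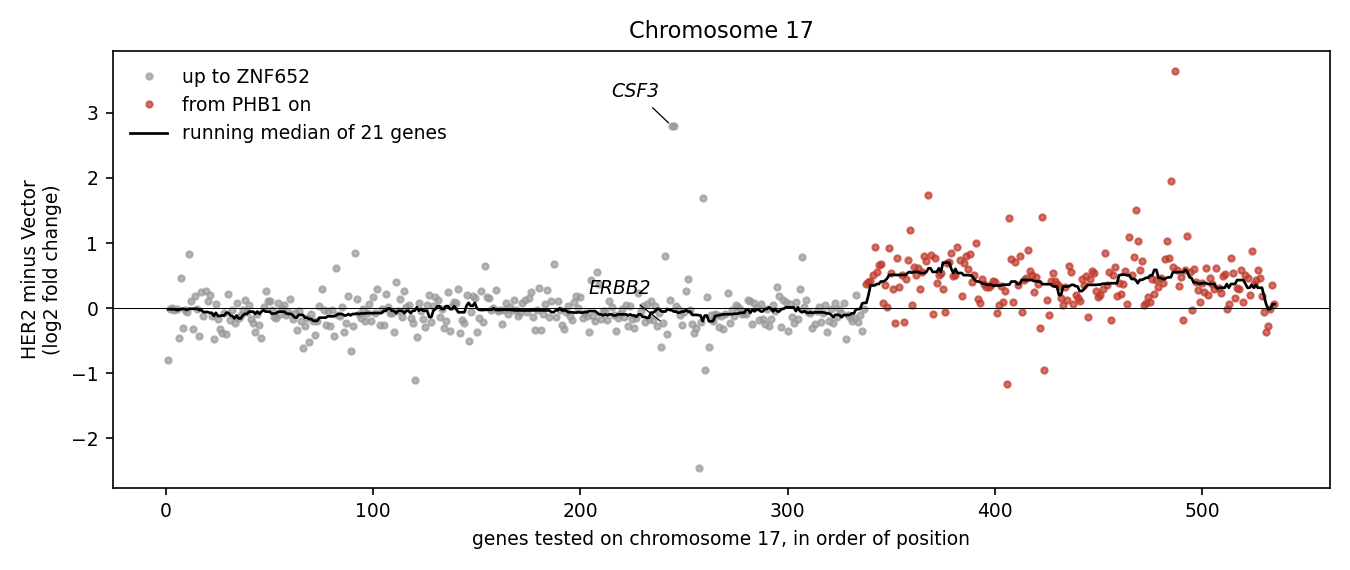
Log2 fold change, HER2 minus Vector (y axis), of the genes tested on chromosome 17 in order of position (x axis), grey up to ZNF652 and red from PHB1 on, with a running median of 21 genes in black. The red genes have a median of 0.42 and the grey genes one of -0.06, and ERBB2 and CSF3 lie among the grey genes.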

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

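The rule for outlying samples was set before the data were examined, and no test in this part was chosen after its result was seen. For 89 genes the 4 samples of each group were compared, and 13 of the 178 groups (7.30%) held a sample far from the other members, where chance gives about 1 in 20. Vector replicate 4 was the sample in 7 of them, all above the others of its group (log2 intensity): KRT15 read 12.96 there and 11.53 to 11.74 in the other Vector samples, MGP 9.44 (7.78 to 8.02), FBLN1 9.19 (7.93 to 7.97), KLK7 8.38 (6.55 to 6.66), NCCRP1 8.81 (7.15 to 7.29), ITGB4 9.16 (8.32 to 8.45) and CD14 9.14 (8.07 to 8.23). HER2 replicate 1 was the sample in 4: PDZK1IP1 read 7.44 there and 8.24 to 8.40 in the other samples labelled HER2, TAP1 9.59 (9.88 to 9.93), ABCC3 10.38 (10.90 to 10.97) and CCNE1 7.82 (7.23 in each). Vector replicate 3 was the sample in 2, ALOX5AP at 7.65 (5.62 to 5.88) and CXCL8 at 4.94 (4.30 to 4.33), where CXCL8 was below background on all 4 Vector arrays, so its readings do not mark that sample.

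Probes that the annotation used here does not name also differed between the groups. Of 2654 such probes above background, 95 passed in limma adjusted over all detected probes, 53 higher and 42 lower in the samples labelled HER2, with log2 fold changes from -1.63 to 2.99.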

How the results depend on the processing

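The test without the distal chromosome 17 genes was chosen after the result was seen, and the other alternatives before. ERBB2 passed in 0 of them; with 1 array left out its difference lay between -0.32 and -0.10. No reported direction reversed, while 1 gene outside those named turned sign when only probes detected on all 8 arrays were used. The count of genes past the threshold (602; 384 higher, 218 lower; 208 at least 2-fold) was 247 (174 higher, 73 lower) against a fold of 1.2, where the stricter null is the cause. It was 377 (249 higher, 128 lower) with means per experiment number and 283 (203 higher, 80 lower) with means per replicate label, which leave 2 values per group. Median scaling gave 139 lower and array weights 343 lower; the cause was not tested. Genes at least 2-fold apart numbered 97 without background correction, 128 with an offset of 50, 105 with the authors' values and 125 with probes detected on all 8 arrays, a filter that removes the genes dim in 1 group. With the replicate number as a block 930 genes passed (387 lower), 600 of them shared with the fit without it; the deviations of same-numbered samples from their group means correlated across genes at 0.39, 0.12, 0.04 and 0.46, and Vector replicates 2 and 3 correlated best with HER2 replicate 1, so the numbers were not taken as pairs. The protease list did not pass with that block (adjusted p = 0.0574), and no other list call changed. With 1 array left out, 373 (without HER2 replicate 2) to 596 (without Vector replicate 4) genes passed, 253 to 396 higher and 120 to 200 lower, 141 of the latter without Vector replicate 2. The number of lists past the threshold, 7, was 2 with an estimated correlation, 6 with fry, and 6 to 8 with 1 array left out, the DNA replication list being gained without Vector replicate 4. With genes detected on all 8 arrays the ERBB and squamous lists were gained, the interferon and protease lists lost and the NF-kB list not tested, with members left out by their level in 1 group. Without the distal chromosome 17 genes 496 genes and 6 lists passed. Of 88 named genes, 3 (PGAP3, RIGI and CCN2) lost their call without background correction, and the same 3 with the authors' values. With median scaling 6 lost it: PGAP3, MYC, KRT7, DKK1, TNFRSF10B and NQO1. The call was lost by 16 without the filter on dim probes, 20 against a fold of 1.2, 14 with means per experiment number and 20 with means per replicate label. With the authors' values 35 differed by over 1.5 times less: signal over background limits the size of the fold. With 1 array left out, none of the 88 that passed moved by over 1.5 times, while 4 of the 88 that did not pass did: CCNE1 (-0.44; -0.29 without Vector replicate 1, -0.69 without Vector replicate 4), GPAM (0.42; 0.28 without Vector replicate 2), ACLY (-0.20; -0.11 without HER2 replicate 1) and TYMS (-0.48; -0.32 without Vector replicate 3). ERBB2, which is not among the 88, also moved by more, from -0.23 to -0.10 without Vector replicate 4. The fold test and the random block gave no list values, and the array chip as a block was not run because the columns name no chip.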

Other observations

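The tests in this part were chosen after the results were seen, except the splits for the counts of genes, of lists and of experiment differences. The comparison of dim, middle and bright genes of distal chromosome 17 was chosen after the shift there was seen, though before its own result. The genes of this and the next paragraph were also chosen after their values were seen, as single genes, and no group of genes was tested through them. Among genes outside the fixed lists that rose in the samples labelled HER2 (limma, log2 fold change ± SE, n = 4 each) were the receptor-associated kinase IRAK2 (3.38 ± 0.21; adjusted p = 1.91e-06), the ribonuclease ZC3H12A (2.90 ± 0.25), TNIP1 (2.33 ± 0.18) and NFKBIZ (2.21 ± 0.40). CFB rose at least 5.42-fold, LRG1 (detected on 1 Vector array) by 2.54 ± 0.20, C3 by 1.13 ± 0.13 and SERPINA1 (on 3) by 1.10 ± 0.15. So did the interferon-gamma receptor subunit IFNGR1 (1.72 ± 0.18), the transcription factor IRF1 (1.18 ± 0.17) and the protease CASP1 (1.72 ± 0.16).

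VCAN (2.39 ± 0.18, log2, SE), COL8A1 (2.10 ± 0.38) and COL12A1 (1.86 ± 0.28) were higher in the samples labelled HER2, and COL7A1 (-1.15 ± 0.19), the serine protease HTRA1 (-1.54 ± 0.19) and IGFBP3 (-1.61 ± 0.41; its other probe, at -1.19 ± 0.39, did not pass) were lower. MED24, beside CSF3 on chromosome 17, rose by 2.80 ± 0.12, and PSMD3, the neighbour on the other side of CSF3, differed by 0.13 ± 0.17. In the scan of gene order, the lowest median of 41 neighbouring genes was -0.22, between REXO4 and TUBB4B, and 8 of 1000 shufflings of gene order had one as low (permutation p = 0.009, with genes as units, which are not independent).

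Other splits of the samples were examined, 35 in all, each of the 8 samples into 4 and 4. The real split called 602 genes and the next highest 12. The real split alone called as many, 1 of 35, the smallest share that 35 splits can give. The other splits mix the groups, so the difference between the groups adds to the spread within them. The share therefore describes these splits and does not by itself exclude chance, for the count of genes or for any other value compared over them. For the count of lists chance was not excluded: the real split called 7, 8 of the 35 splits called as many, and the highest other, the split by replicate label, called 11; with the label as a block 7 lists passed. With an estimated correlation the real split called 2 lists and the others 0 (1 of 35 as many). For the experiment numbers 18 exchanges within groups are too few for a share under 0.05; the real labels gave 0 genes and the highest other 49, and 18 of 18 gave as many as the real ones.

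ERBB2 did not read higher in the samples labelled HER2. An exchange of single samples between the groups is argued against, since 0 of the 8 arrays correlated better with the other group than with its own. An exchange of all labels would leave that count at 0, and it stays open, since ERBB2 did not pass in either direction. Probes that lie outside the introduced cDNA are a candidate explanation that stays open: the detected probe differed by -0.23, and without its sequence no value decides whether it reads the cDNA.

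The NF-kB list rose with a median of 2.80 over the 17 members past the filter on dim probes, and of 1.504 over all 24 with a probe. Over the 17 members, the median was 1.55 with the authors' own values, which keep the background. That argues against the background correction used here as the whole cause. The authors' values also appear normalized by quantiles, so they do not test the normalization. In the lower of the experiment numbers the median was 2.67, which argues against the handling of 1 experiment. Leukocytes among the cells of the samples labelled HER2 stay open: the median change of 13 leukocyte markers was 0.0124, but 10 of them were below the filter on dim probes, and of the measured ones CD14 rose by 1.78 while CD68 differed by -0.03. The next highest median among the 35 splits was 1.44, and 1 of 35 was as large. Since the other splits mix the groups, that share does not by itself exclude chance. An effect of the introduced HER2 may underlie the rise, a hypothesis that these arrays leave open, as they do a difference between cell populations that arose apart from HER2.

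The upward shift of distal chromosome 17 was noticed by scanning gene order in these data, and its boundary was set from them. The highest median of any 41 neighbouring genes was 0.56, reached between SPATA20 and INTS2. In 1000 shufflings of gene order it was at most 0.24 (permutation p = 0.001, the smallest they can give). The shufflings take genes as independent units, which they are not. Other splits of the 8 samples, each searched anew, reached at most 0.34 (1 of 35 as large). Those splits mix the groups, so that share does not by itself exclude chance. Brightness is argued against by 10000 lists matched on intensity, whose highest median was 0.0348, and 1 deviating array by a lowest median of 0.39 with 1 array left out. An extra copy of this part in the cells of the samples labelled HER2 is a candidate explanation. It predicts a shift at every brightness, and the lowest median among dim, middle and bright genes was 0.37. The part was chosen for lying high in these data, so that result was largely set in advance. It does not tell an extra copy from another shift of the region. The values are relative, so they do not tell which group's cells would have changed. DNA was not measured here, so a copy change was not tested directly, and whether it would have arisen by chance in the transduced cells or through HER2 stays open.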
